A study of Caenorhabditis elegans with 4 samples.

How the data were processed

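Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on fed first-stage (L1) hermaphrodite larvae of the nematode Caenorhabditis elegans, grown at 20 °C. The strain, OP106, carries an integrated transgene that encodes MDL-1 fused to EGFP and FLAG tags, together with a rescuing copy of unc-119. MDL-1 is a Mad-like basic helix-loop-helix leucine zipper transcription factor. Per the labels, 4 libraries were made: 2 from DNA recovered with a goat anti-GFP antibody and 2 from input DNA, in replicates numbered 1 and 2. Per the labels' protocols, worms were crosslinked with formaldehyde, chromatin was sheared by sonication, and the recovered DNA was size selected on a gel before Illumina library preparation.

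The peak list analysed is named as combined and was taken to combine both replicates. Peaks were called with PeakSeq in coordinates of WormBase WS180, per the file headers and source column. The aligner, the PeakSeq version, the read filters and the way the replicates were combined are not given in the sources used here. Each peak has a first and a last base, counted from 1, and a q-value that the authors deposited both in the score column and as an attribute. The 2 copies were identical for all 9533 peaks. The deposited q-values were below a threshold of 0.01 in every peak. Multiplied by the place of the peak in the list they never stepped down, so the list is ordered by an underlying p-value. The q-values alone stepped down 5558 times along the list, so their order is not exactly that of the list. Read counts, fold enrichments and values per replicate were not used here, so the depth is unknown, no value below has a replicate error, and no statement can be made on the agreement of the replicates.

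Peak strength was taken as -log10 of the deposited q-value, and all strengths below come from the authors' deposited table in this way. Peak width was the last minus the first base plus 1. Chromosome lengths of WS180 were not used; densities were computed over the span from the first to the last peak of each chromosome, and the central 50% and the outer 25% at each end were parts of that span. Peak counts per chromosome were compared with the spans by a chi-square statistic, with p from 100000 multinomial draws, and Poisson intervals of 95% (exact) were given per chromosome; these cover counting error only and treat peaks as independent. Because peaks cluster, the ratio of X to autosomes was given a 95% interval from 10000 bootstrap draws of 500 kb windows. Medians of strength and width were compared by two-sided permutation tests with 100000 permutations (10000 within strength classes and for alternatives), with 95% bootstrap intervals from 2000 draws and Benjamini-Hochberg adjustment within each family. These permutation tests also treat single peaks as independent. Spacing was compared with 1000 random placements in which each 500 kb window kept its peaks and their widths, at least 200 bp apart. Strength-adjusted width was the log2 width minus the mean log2 width of peaks in the same of 20 equally filled strength classes.

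Before the data were examined, the tests of peak number per chromosome and of strength on X and in chromosome centres were fixed, as were the stricter and merged alternatives and the rule for named items. That rule named genes next to the 20 strongest peaks or, where genes could not be assigned, the 10 strongest peaks by position, and the 5 widest peaks. The gene table at hand is of assembly WBcel235, another build than that of the peaks, so no peak was assigned to a gene. The planned comparisons with gene starts, annotation classes, 32 gene lists and the CACGTG E-box were therefore not run. Comparisons of peak width on X, of peak density along chromosomes and of spacing, and the classes by width and strength, were added after the list had been seen.

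The procedures were tested on simulated data. In 20 simulated lists of 9533 peaks with an X to autosome ratio of 0.6, the mean recovered ratio was 0.607 and the interval held the true value in 19 lists. Simulated peaks were placed independently along each chromosome, whereas the variance to mean ratio of observed counts per 500 kb window was 6.22. How often the interval holds the true value for clustered peaks was therefore not tested. A shift of 0.3 in the strength of X peaks was recovered as 0.315 on average and passed p of 0.05 in 5 of the 20 lists, so shifts of that size are mostly missed. In 20 simulated X chromosomes of 1078 peaks with a 1 Mb stretch whose log2 width was shifted by -1.3, both ends of the stretch were placed within 200 kb in 17. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.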

Results

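The binding of the transcription factor MDL-1 was mapped in fed L1 larvae with a GFP-tagged transgene. The question addressed was where in the genome the tagged protein is found at this stage, with 2 anti-GFP libraries set against 2 input libraries. The result was one list of 9533 binding regions over the 5 autosomes and the X chromosome. Together they covered 3262362 bases, or 3.26% of the 100004995 bases between the first and last peak of each chromosome. The median width was 285 bp, with quartiles of 191 and 410 bp and extremes of 1 and 5005 bp. The median strength, -log10 of the q-value in the authors' deposited table, was 5.10, with quartiles of 2.96 and 11.1. Strengths above 10 were found for 2659 peaks (27.9%) and above 100 for 81, while 2466 peaks (25.9%) had a strength below 3. Wider peaks were stronger: across peaks, which are not independent replicates, Spearman's rho of width and strength was 0.76 (permutation p = 1e-04, the smallest that 10000 permutations can give). The 260 peaks wider than 1000 bp had a median strength of 45.6, against 2.43 for the 567 peaks under 50 bp. A stricter choice of peaks therefore also selects wider ones.

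The strongest peaks, as ranked by q-value, were spread over all autosomes. Of the 10 strongest peaks 3 lay on chromosome II, 3 on V, 2 on III and 1 each on I and IV, and none on X. Positions are in WS180 and were not assigned to genes. The first, on chromosome V from 11887695 to 11889942, had a q-value of 1.64e-238 in the authors' deposited table. The second, on II from 8741812 to 8745964, was 4153 bp wide and had a q-value of 2.22e-211 in the authors' deposited table. The third, on III from 4649204 to 4649865, reached a q-value of 2.72e-211 in the authors' deposited table over only 662 bp, and was the only one of the 10 narrower than 1000 bp. The other two on V lay from 13657316 to 13659554 (strength 206.2) and from 5843398 to 5846270 (strength 195). Those remaining on II lay from 9603264 to 9604424 and from 11634006 to 11636173, both with a strength of 193. The others were found on IV from 11956233 to 11957540 (strength 185), on III from 4280282 to 4282856 (strength 179) and on I from 7081407 to 7083978 (strength 178). The strongest X peak ranked 18, and 15 of the 100 strongest peaks were on X.

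Among the 5 widest regions, 1 was also among the 10 strongest, the region on II that starts at 8741812. The widest extended over 5005 bp on I from 14755569 to 14760573 and ranked only 221 by strength (58.8). The others were a region of 4820 bp on II from 10544877 to 10549696 (strength 172), one of 4453 bp on V from 723864 to 728316 (strength 129) and one of 3991 bp on V from 15566079 to 15570069 (strength 136).

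MDL-1::GFP peaks were unevenly shared between chromosomes, densest on III and sparsest on X. Chromosome III held 1704 peaks, or 124 per Mb (95% exact Poisson interval 118 to 130), and chromosome II 1758, or 115 per Mb (109.8 to 121). Chromosome I held 1527 peaks at 101 per Mb (96.3 to 107), IV held 1620 at 92.9 per Mb (88.4 to 98) and V held 1846 at 88.3 per Mb (84.3 to 92.4). Chromosome X held 1078 peaks, 61.4 per Mb (57.8 to 65.1), where its span would give 1675. The counts departed from the spans over the 6 chromosomes (chi-square 411, multinomial permutation p = 1e-05, the smallest that 100000 draws can give) and over the 5 autosomes alone (chi-square 142, p = 1e-05 by the same draws). They did so as well after peaks within 1 kb were merged into 7592 regions (chi-square 247, p = 1e-05).

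**Figure D1:**
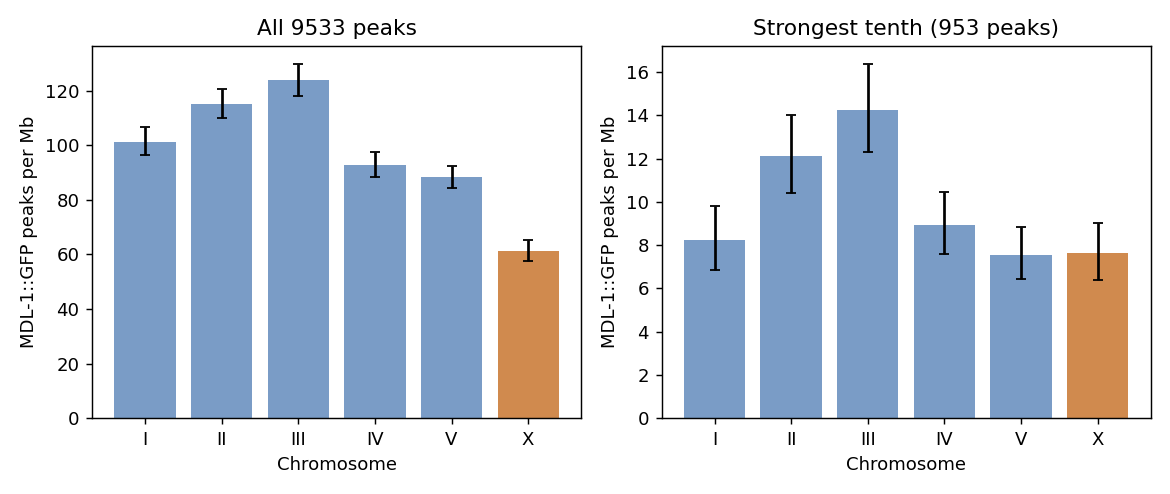
MDL-1::GFP peaks per Mb of each chromosome's span, for all 9533 peaks (left) and for the strongest 953 (right). Bars are densities of the single combined list, with 95% exact Poisson intervals; among all peaks X lies lowest at 61.4 per Mb, while among the strongest it lies at 7.63 per Mb, near the 7.56 per Mb of V.

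X carried 0.60 times the autosomal density of 103 peaks per Mb (95% interval 0.53 to 0.67 from resampled 500 kb windows). The mean number of peaks per 500 kb window was 30.4 ± 9.35 (SD, n = 35 windows) on X and 51 ± 16.3 (SD, n = 162 windows) on autosomes (two-sided permutation test of windows, p = 1e-05, the smallest possible). This test and the window intervals treat windows as independent. With a single X chromosome, they do not measure the spread between chromosomes. The ratio of the median windows, 29 peaks on X and 52 on autosomes, was 0.56 (95% interval 0.52 to 0.62). Against single autosomes the ratio of densities ran from 0.50 for III to 0.70 for V. By strength, the ratio was 0.46 (95% interval 0.39 to 0.53) in the weakest 25% of peaks, 0.61 (0.50 to 0.74) and 0.65 (0.57 to 0.74) in the next classes of equal size, and 0.67 (0.57 to 0.78) in the strongest 25%. It was 0.66 (0.58 to 0.75) among above-median peaks and 0.77 (0.62 to 0.91) in the strongest 10%. The differences between these ratios were not tested. In the strongest 10% X had 7.63 peaks per Mb (exact Poisson interval 6.39 to 9.03), V 7.56 (6.42 to 8.83), I 8.23 (6.85 to 9.81) and IV 8.95 (7.60 to 10.5), whereas II had 12.1 (10.4 to 14) and III 14.2 (12.3 to 16.4).

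Peaks on X were wider than those on autosomes, also at equal strength, so its density relative to autosomes differed by width class, and these classes do not locate the deficit. Of the 2591 peaks narrower than 200 bp, 84 were on X, a density 0.16 times that of the autosomes (95% interval 0.11 to 0.21). The ratio was 0.59 (0.51 to 0.67) from 200 up to 400 bp, 1.14 (0.96 to 1.31) from 400 up to 800 bp and 1.28 (0.98 to 1.64) from 800 bp. The median X peak was 381.5 bp wide and the median autosomal peak 272 bp, a difference of 109.5 bp (95% interval 96 to 123, permutation p = 1e-05, adjusted p = 5e-05 over 5 tests). In the weakest 25% of peaks the medians were 272 bp on X and 138 bp on autosomes, and in the strongest 25% they were 545 and 458 bp (permutation p = 1e-04 in each of the 4 strength classes, the smallest possible; adjusted p = 1e-04). X peaks covered 2.83% of its span and autosomal peaks 3.36% of theirs, a ratio of 0.84.

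**Figure D2:**
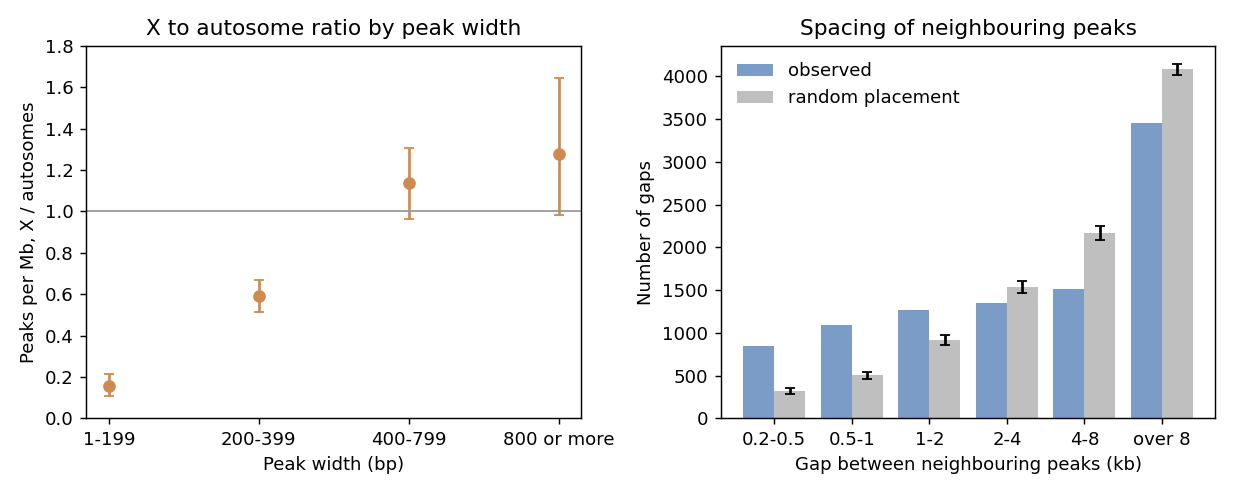
Left, ratio of peaks per Mb on X to that on autosomes (points, with 95% intervals from resampled 500 kb windows) by peak width in bp; it rises from 0.16 for peaks under 200 bp to 1.28 from 800 bp. Right, number of gaps between neighbouring peaks by gap length in kb, observed and in 1000 random placements (mean, with the range that holds 95% of placements); gaps of 200 to 500 bp numbered 850 against 317 by placement.

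The width of X peaks was shared along nearly the whole chromosome, with 1 exception. In 17 of its 18 segments of 1 Mb the mean strength-adjusted log2 width lay between 0.40 and 0.81, above each of the 85 autosomal segments, whose highest was 0.37. In the segment from 6 to 7 Mb it was -0.73 ± 0.19 (SE, 48 peaks), below the lowest full autosomal segment at -0.54. Among autosomal end segments that were not full, that of II lay at -0.62 ± 0.18 (41 peaks). That of I lay lower, at -1.18 ± 0.73, with only 6 peaks. The other such end segments lay higher, from -0.25 to 0.23. The median width in the X segment from 6 to 7 Mb was 216.5 bp. Of its peaks, 41.7% were narrower than 200 bp, against 6.21% on the rest of X and 29.7% on autosomes. The other X segments had median widths of 351 to 426 bp.

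**Figure D3:**
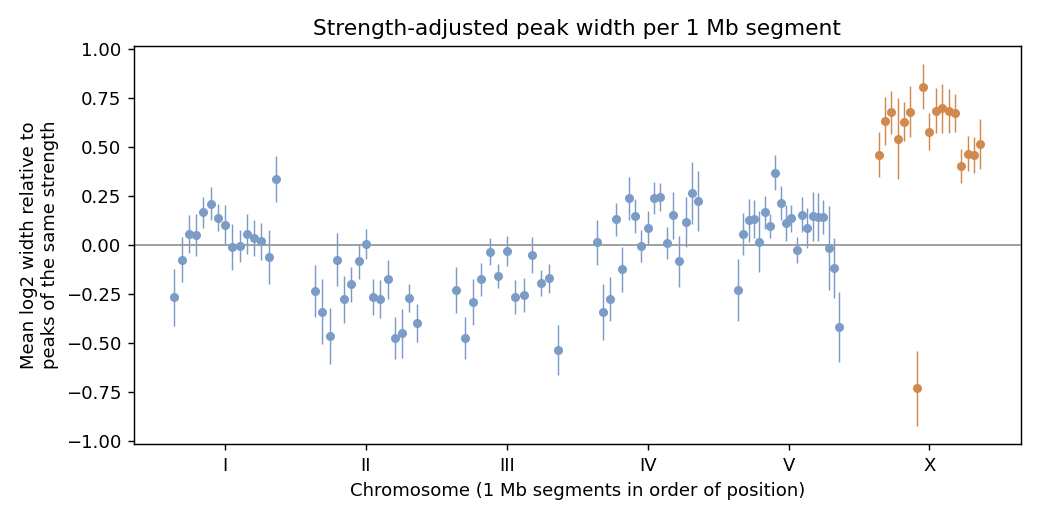
Mean log2 peak width relative to peaks of the same strength, for each full 1 Mb segment in order of position on each chromosome (points, with the standard error over the peaks of the segment). The X segments lie above the autosomal ones except for that from 6 to 7 Mb, at -0.73.

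Peaks on X were also stronger than autosomal peaks by a small margin. The median strength was 5.66 on X (1078 peaks) and 5.0 on autosomes (8455 peaks), a difference of 0.66 (95% interval 0.23 to 1.16, permutation p = 0.0032, adjusted p = 0.0032 over 2 tests). X peaks were wider by the margin given above, and width and strength rise together. Single autosomes had medians from 4.68 on V and 4.70 on IV to 5.39 on I and 5.42 on III, so they differed among themselves by more than X differed from all of them. With peaks within 1 kb merged the difference was 0.54 and fell short of the threshold (permutation p = 0.053). Among above-median peaks, a set chosen by strength itself, it was 0.14 (permutation p = 0.75). By the percentile of the place in the list, the difference was 4.59 (permutation p = 0.0054).

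On autosomes, peaks in the central 50% of the span were slightly stronger than those in the outer parts, with medians of 5.19 (4812 peaks) and 4.77 (3643 peaks). The difference was 0.42 (95% interval 0.15 to 0.74, permutation p = 0.0030, adjusted p = 0.0032). Both the interval and the p-values treat single peaks as independent and do not measure the spread between chromosomes. Within single chromosomes the difference was 1.22 on III, 0.77 on V, 0.64 on I and 0.43 on IV, and -0.45 on II. Among above-median peaks, again chosen by strength, the difference was -0.00040 (permutation p = 0.99). With peaks within 1 kb merged it was 0.62 (permutation p = 0.0013). By the percentile of the place in the list it was 3.41 (permutation p = 0.0012).

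The density of peaks was higher in the centre than outside it on each of the 5 autosomes and lower on X, a difference that the test over chromosomes could not decide. The central 50% of V held 107.8 peaks per Mb and its outer parts 68.8, a ratio of 1.57. The ratio was 1.35 on II, 1.26 on III, 1.23 on I and 1.20 on IV, and 0.92 on X, with 58.7 peaks per Mb in its centre and 64 outside. Over the 6 chromosomes the geometric mean ratio was 1.24 and did not pass an exact sign-flip test (two-sided p = 0.0625). The smallest possible p, 0.031, needs all 6 ratios on the same side of 1. With X below 1, no size of the autosomal ratios could have given a p under 0.0625, so no conclusion is drawn from this test. The densest 500 kb windows, with 90 peaks each, began at 5514754 on III and at 6006266 on V. The sparsest, with 7 peaks, began at 17006266 on V. The longest stretch without a peak, 280483 bp, also lay on V, from 16966155 to 17246637. Of the 43 stretches over 100 kb without a peak, 18 were on X, 13 on V, 9 on IV, 2 on II and 1 on I, and none on III.

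**Figure D4:**
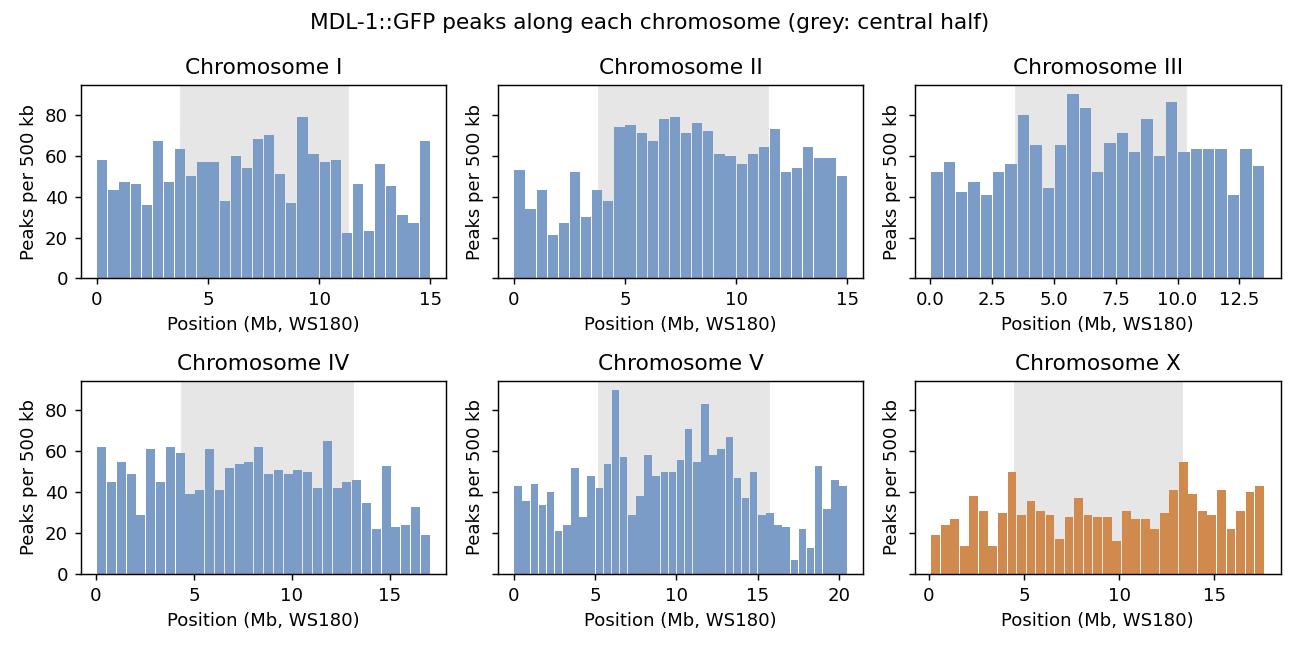
Number of MDL-1::GFP peaks in consecutive full 500 kb windows along each chromosome (position in Mb, WS180), with the central 50% of the span shaded. Windows hold between 7 and 90 peaks, with a median of 48.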

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

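All alternatives with the segment of X left out, each autosome left out, the strongest 10% of peaks, merging for strength, and those for width on X, density and spacing were chosen after seeing the data. The X to autosome ratio of peak density stayed below 1 in each alternative run, from 0.57 without chromosome V to 0.77 in the strongest 10%. It was 0.66 among above-median peaks and 0.61 without the X segment from 6 to 7 Mb. The classes by width, which are not among these alternatives, ran from 0.16 for the narrowest peaks to 1.28 for the widest. The number of peaks was 4767 in the above-median set and 8681 after merging within 500 bp, and the median width moved from 285 to 382 and 295 bp in these. The higher strength of X peaks was 0.539 with peaks within 1 kb merged, with a permutation p of 0.053; the cause was not tested. Among above-median peaks the difference in strength was 0.137 on X (permutation p = 0.75) and -0.00040 in autosome centres (permutation p = 0.99), so neither passed the test there. These sets were chosen by strength itself, so both values cover only the upper part of the strengths. With the percentile of the place in the list as strength, both differences were kept. They were 4.59 on X (permutation p = 0.0054) and 3.41 in autosome centres (permutation p = 0.0012). The place in the list follows the p-value that underlies the q-value, so this alternative is no independent check. Autosome centres also kept a difference of 0.62 with peaks within 1 kb merged (permutation p = 0.0013). X without its segment from 6 to 7 Mb kept one of 0.66 (permutation p = 0.0039). The wider X peaks kept their difference, from 95 to 116 bp over 3 alternatives. No paired analysis was possible because the peak list, taken to combine both replicates, holds no value per library. For the same reason no replicate could be left out. The alternatives for gene starts, annotation classes, the E-box and gene lists were not run, since no annotation of the build of the peaks was used here. Depth is unknown, so how many weaker sites lie below the threshold cannot be given.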

Other observations

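MDL-1::GFP peaks were grouped at short range. The median gap between neighbours was 4413 bp and the smallest 200 bp. Whether close peaks are separate sites or pieces of 1 enriched region was not tested. Gaps of 200 to 500 bp numbered 850 against 317 in random placement within 500 kb windows, a ratio of 2.68, and the ratio was 2.17 for gaps of 500 to 1000 bp and 1.38 for gaps of 1 to 2 kb (one-sided permutation p = 0.001 for each, the smallest that 1000 placements can give). Gaps of 4 to 8 kb were fewer than placed, with a ratio of 0.70. Of all peaks, 3267 (34.3%) had a neighbour within 1 kb. These were stronger than the 6266 without one, with median strengths of 5.81 and 4.80 (difference 1.02, 95% interval 0.70 to 1.34, permutation p = 1e-05, the smallest possible). They were also wider, with median widths of 314 and 274 bp, and width and strength rise together. Within the 1941 such neighbouring pairs the strengths were only weakly related (Spearman's rho 0.10 across pairs). The largest groups held 12 peaks each, on V from 6220884 to 6233314, with a strongest member of 134, and on III from 7722539 to 7731372, with a strongest member of 29.5. A group of 11 peaks spanned 16242 bp on V from 10711745 to 10727986, with a strongest member of 127.

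The tests of the ends of the X stretch and of the strongest 25% of peaks were chosen only after the result was seen; the other tests below, that of the strongest 10% included, were written down before their values were known. No biological explanation was tested for any of the patterns below, since the libraries differ only in antibody enrichment and replicate.

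For the width of X peaks and its single exception, a candidate explanation is a height threshold that the peak caller sets separately for segments of 1 Mb and that was lower on most of X, so that the same enrichment gave a wider region. The stretch of X whose strength-adjusted width deviated most ran from the peak at 5978266 to the peak that ends at 7068704 (51 peaks). With the gaps to the next peaks, its ends lay at most 46.5 and 100.3 kb from multiples of 1 Mb, and 2 random ends would lie within the larger of these distances with a probability of 0.040; this stays open, as the stretch was first noticed on a 1 Mb grid, so its ends are no independent test. The adjusted width of its segment, -0.73 ± 0.19 (SE), lay below all 80 full autosomal segments, which ran from -0.54 to 0.37. It was about 1 SE below the lowest of them and farther below the others, where a threshold lower only on the rest of X would leave it like autosomes. The end segments of II and I, which were not full, lay at -0.62 ± 0.18 (41 peaks) and -1.18 ± 0.73 (6 peaks). The X segment was therefore not the lowest of all segments, and whether it is unlike autosomes stays open. Whether extra copies of a locus carried by the transgene raised the read density there also stays open, since no read counts and no gene positions in this build were used. For thresholds that vary among autosomal segments, the grid starting at base 1 ranked 10 of 10 offsets by variance between autosomal windows. That share of variance ran only from 4.01% to 4.44% over the offsets, and its spread without any threshold effect was not estimated. On X, with its deviating segment, the same start ranked 2 at 9.35%, close to the highest at 9.42%. The autosomal rank therefore gave no support to this explanation but cannot exclude it.

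For the lower density of X peaks, splitting of autosomal regions into more pieces is argued against. Regions merged within 1 kb still gave a ratio of 0.66 (95% interval 0.59 to 0.72), below the bound of 0.9 set before this value was known. A few very dense autosomal windows are argued against as well, since the ratio of the median 500 kb windows was 0.56 (0.52 to 0.62). A loss confined to weak X peaks at the q-value threshold is argued against as the whole cause. The strongest 25% of peaks, with strengths above 11.1, still had a ratio of 0.67 (0.57 to 0.78). The strongest 10%, at 0.77 (0.62 to 0.91), did not exclude the bound of 0.9 by themselves. That test was written down before its value was known, but after the list had been seen. These classes were cut on strength itself, so they cannot show whether strength was lowered on all X peaks. The ratio was lowest, 0.46, in the weakest 25%. A part of the deficit from weak peaks, and a difference in mappability or background of X, stay open.

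The width of exactly 200 bp was given to 192 peaks, 9.27 times the mean of 20.7 at each other width from 150 to 250 bp, of which the highest was 34. Weak regions, as stacks of reads at 1 position extended to a fixed length would give, may contribute: the median strength of the 200 bp peaks was lower by a difference of -0.19 (95% interval -0.38 to -0.0045), but the permutation test gave p = 0.12, so this stays open. A concentration in a few places is argued against, since 21.9% of these peaks had another within 50 kb, inside the range of 13.5% to 28.6% of 10000 random draws of peaks of similar width.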
